A study of Juglans regia with 18 samples.

How the data were processed

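Leaf RNA of walnut seedlings was measured in 18 libraries, 3 in each of 6 groups: water control, 100 mM NaCl, and 100 mM NaCl with Pseudomonas strain P1, P2, P3 or P4. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, the libraries were strand-specific, made from polyA-enriched mRNA starting from 100 ng of total RNA, and sequenced on an Illumina instrument. The submitters' processing notes name STAR 2.7.10a and featureCounts 2.0.3, without parameters. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. The deposited values are raw read counts per gene, per the file headers, in one table with a column per library. They were whole numbers with totals of 21192350 to 27462583 per library, were not normalised, and were used as deposited. Genes that share reads with a near-identical copy, and overlapping or antisense genes, could not be marked and are uncertain.

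The table holds 39414 gene identifiers and does not pair them with names. Of these, 0 matched the RefSeq gene table of the walnut assembly Walnut 2.0, which holds 37996 genes. The 50 gene lists and the cell type markers that had been fixed as patterns on product names could therefore not be tested. At most 2 identifiers in each direction are printed for salt against control and for the mean of the strains, and 1 in each direction for a single strain. The naming rule took the largest log2 fold changes among genes with adjusted p below 0.05, a mean of at least 5 CPM over the libraries compared, and no overlap between the libraries of the groups, a condition that 10% of genes meet by chance with 3 against 3 libraries. Its condition of a product name could not be applied.

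Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr (minimum count 10, minimum total count 15) were kept, 24287 in all, and libraries were scaled by TMM factors. One quasi-likelihood model with 6 group means was fitted to the 18 libraries, and contrasts were tested with glmQLFTest. Calls had a Benjamini-Hochberg adjusted p below 0.05, and the words higher, lower, rose and fell refer to such calls. A change of 2-fold or more is a called gene whose fitted log2 fold change has a size of at least 1. CPM values of single genes use the TMM-scaled library sizes. Where a group had no read, the fold was computed against 3 counts over the group. With 1 to 9 counts, the ratio is given with a 95% interval, which covers counting error only. Reads had no molecular identifiers.

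Positions between control and salt were computed per library from log2 CPM with a prior count of 2, as the distance from the control mean divided by the distance between the salt and control means, for genes changed 2-fold or more by salt. The median over genes was taken in each library, and strains were compared by exact permutation tests. Principal components were computed on the same log2 CPM. Comparisons that share the salt libraries were set against 20 simulations of groups drawn at the salt level. Replicate libraries were compared by a chi-square test of their counts. Its value per degree of freedom was 1.93 to 3.63 within groups and at least 37.1 between groups, so no pair agreed within sampling noise and each library counted as 1 sample.

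The procedure was tested on simulated counts for 24287 genes. For salt against control, 44%, 68%, 88% and 92% of 50 genes each changed by 1.25, 1.5, 2 and 4-fold were recovered, with 12 false calls, 7.59% of the calls. For P1 against salt the shares were 34%, 64%, 90% and 94%, with 11 false calls. Over the simulated comparisons, false calls made up from 4.03% of the calls with P3 to 8.28% with P4. In this simulation all groups started at the salt level, and only these genes were changed, as many raised as lowered. It therefore does not test the scaling, or the false calls, where most genes are called, as in these data. Positions simulated at 0.25, 0.5, 0.75 and 1 were recovered at 0.249, 0.497, 0.748 and 0.998 over 9554 genes. A group simulated as a mix of control and salt RNA in a share of 0.5 gave a median share of 0.4998 and a median distance of single genes of 0.739 standard errors over 9577 genes. The main design and the first alternatives were fixed before the data were examined: DESeq2's size factors, DESeq2 1.42.0, no filter, a stricter filter (1 CPM in at least 6 libraries), a replicate block, each library left out and a fit of the groups compared alone. Library size only, a test against a 2-fold change (glmTreat), a prior count of 0.5, the positions, the counts of changes of 2-fold or more and the gene sets built from them were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.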

Results

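Leaf RNA of walnut (Juglans regia) seedlings was sequenced in 6 groups of 3 libraries, 18 libraries in all. One group received water (control), one received 100 mM NaCl (salt), and the other 4 groups received 100 mM NaCl together with one of the Pseudomonas strains P1, P2, P3 or P4, each being a bacterial isolate used to inoculate the seedlings. The labels give no inoculated group without salt, so each strain was measured under salt only. Total read counts per library ranged from 21192350 to 27462583. Of the 39414 genes in the table, 8962 had no read in any library and 24287 were tested. The labels call the 3 libraries of a group biological replicates and do not say whether each came from its own plant. If they came from a shared pool, the p-values measure only the spread between these samples, which may be technical. The biological coefficient of variation was 3.52% over all groups, from 2.72% in P1 to 4.86% in control. Genes carry only the identifiers of the deposited table, which were not paired with gene names, so gene groups are described by their response.

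The 6 groups were separate from each other in the leaf transcriptome. The first principal component of log2 CPM (read counts relative to the scaled library size) held 49.8% of the variance. It placed control at -152 ± 0.520 (SD, n = 3) and salt at 116 ± 0.547, and the 4 strain groups lay between these values, from -22.9 ± 0.0855 in P3 to 47.5 ± 0.122 in P1. The second component held 30.1% of the variance. Control and salt were close on it, at 74.6 ± 0.167 and 75.4 ± 0.229, while P3 lay at -91.3 ± 0.269, P4 at -51.9 ± 0.454, P2 at -31.5 ± 0.306 and P1 at 24.8 ± 0.342. Across genes, which are not independent replicates, libraries of one group correlated at 0.991 to 0.994 and libraries of different groups at 0.805 to 0.971.

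**Figure D1:**
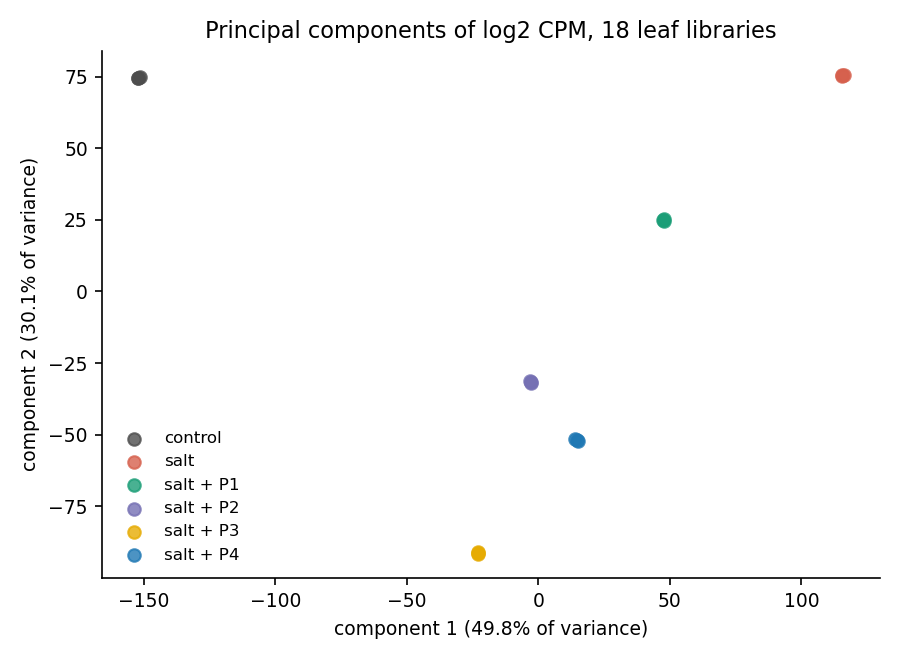
Principal components of log2 CPM, with 1 point per library and the group as colour. Component 1 (49.8% of the variance) separates control from salt, with the strain groups between them, and component 2 (30.1%) separates the strain groups from both; the 3 libraries of a group nearly coincide.

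Salt against control compared uninoculated seedlings given 100 mM NaCl with watered ones. A batch or plant pool shared by a group cannot be separated from salt here. Genes said to be changed by salt are those called in this comparison. A large part of the leaf transcriptome differed: 9871 genes changed 2-fold or more, of which 4623 were higher and 5248 lower in salt. Changes of 8-fold or more were found in 1590 higher and 722 lower genes. The gene JreChr10G11440 had no read in control and 153 ± 1.88 CPM (SD, n = 3) in salt, at least 3849-fold higher when control is set to 3 counts over the group (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.90e-37). JreChr06G11870 rose from 0.121 ± 0.0490 CPM, 9 counts over the group, to 2424 ± 19.8 CPM (edgeR adjusted p = 3.37e-50). The ratio was 20314, with a 95% counting interval of 10701 to 44427. Its fitted log2 fold change was 14.25, and from 14.01 to 14.56 with 1 control library left out. JreChr13G11151 fell from 21.4 ± 2.79 CPM in control to no read in salt, at least 426-fold lower (edgeR adjusted p = 1.79e-22). JreChr09G11482 fell from 22.4 ± 1.28 CPM to 2 counts over the 3 salt libraries, a ratio of 670 with a 95% counting interval of 185 to 5540 (edgeR adjusted p = 1.68e-25). In all, 66 genes without a read in control had a mean of at least 1 CPM in salt, and 19 genes without a read in salt had at least 1 CPM in control.

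The edgeR test called 19762 of the 24287 genes in salt against control, 8877 higher and 10885 lower. The split of directions moved with the scaling of the libraries: with library size only, 34.0% of called genes were higher instead of 44.9%, the median of all genes shifted by -0.266 on the log2 scale, and 3917 genes were 2-fold higher and 6885 lower. With DESeq2's size factors the 2-fold genes divided into 4861 higher and 4850 lower.

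**Figure D2:**
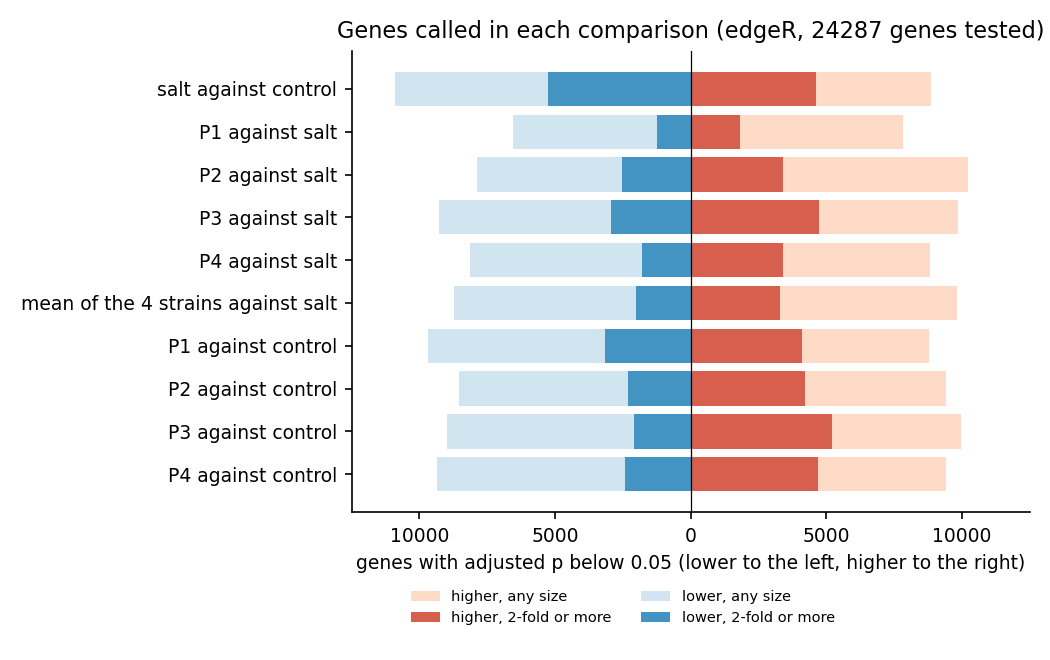
Number of genes called by edgeR in each comparison (adjusted p below 0.05), with higher genes to the right and lower genes to the left; the dark part of each bar holds changes of 2-fold or more. Salt against control has 9871 genes of 2-fold or more, and the comparisons of a strain with salt have from 3054 in P1 to 7649 in P3.

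Each strain against salt compared inoculated salted seedlings with salted seedlings that had no inoculum. A batch or plant pool shared by a group cannot be separated from the inoculum in these comparisons. The number of genes changed 2-fold or more was 3054 with P1 (1804 higher, 1250 lower), 5207 with P4 (3415 higher, 1792 lower), 5915 with P2 (3397 higher, 2518 lower) and 7649 with P3 (4716 higher, 2933 lower). JreChr07G10361 had 3.79 ± 0.386 CPM in control and 1 count over the 3 salt libraries. It reached 20.7 ± 1.34 CPM with P1, a ratio to salt of 1239 (95% counting interval 222 to 48963, edgeR adjusted p = 1.09e-26). With P4 it reached 161 ± 7.0 CPM, a ratio of 9579 (1719 to 378366, edgeR adjusted p = 2.25e-36). Its level was highest with P3, at 184.8 ± 5.50 CPM, and was 15.3 ± 0.957 CPM with P2. Its 1 count lay in salt replicate 1, and without that library the fitted log2 fold change was 12.01 instead of 9.89 with P1 and 14.97 instead of 12.85 with P4, values that depend on the prior count. JreChr03G11397 had no read in control or salt. It reached 56.7 ± 1.86 CPM with P2, at least 1129-fold higher than salt (edgeR adjusted p = 1.39e-28), and 79.2 ± 1.77 CPM with P3, at least 1577-fold higher (edgeR adjusted p = 6.71e-30). Its level was 28.4 ± 0.623 CPM with P4 and 0.0803 ± 0.107 CPM, 6 counts, with P1. JreChr10G11546 showed the opposite course: it had 10.03 ± 0.510 CPM in salt and no read in control, P1, P3 or P4. Against salt it was at least 254-fold lower with P1 (edgeR adjusted p = 1.36e-16), at least 265-fold lower with P3 (adjusted p = 3.08e-17) and at least 243-fold lower with P4 (adjusted p = 8.94e-17). With P2 it had 2 counts, a ratio of 412 (interval 114 to 3411, edgeR adjusted p = 5.62e-17).

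With library size only, the genes changed 2-fold or more divided into 2255 higher and 954 lower with P1, 4675 and 1899 with P2, 6121 and 1951 with P3, and 4059 and 1351 with P4. With DESeq2's size factors they divided into 1668 and 1388, 3086 and 2767, 4524 and 3107, and 3197 and 1999 in the same order. At any size of change, edgeR called 14381 genes with P1, 18106 with P2, 19151 with P3 and 16944 with P4. Higher genes made up 54.6%, 56.5%, 51.5% and 52.1% of these calls in turn. With library size only these shares were 73.0%, 72.2%, 69.6% and 67.6%, with shifts of the median log2 fold change of 0.152, 0.232, 0.295 and 0.165, and with DESeq2's size factors they were 47.0%, 50.8%, 48.9% and 46.0%, so which direction held more calls depended on the scaling with P1, P3 and P4.

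The mean of the 4 strain groups against salt measured the difference from salt that the strain groups had on average. Genes changed 2-fold or more numbered 3296 higher and 2020 lower, or 4212 and 1437 with library size only and 3087 and 2208 with DESeq2's size factors. JreChr07G10361 was the gene with the highest rise under the naming rule, with a fitted log2 fold change of 11.31 (edgeR adjusted p = 2.61e-33). That value averages the log2 levels of the strains. Its counts pooled over the 4 strains gave a ratio of 5617 (95% counting interval 1008 to 221864). This ratio was carried by P3 and P4, at 184.8 and 161 CPM against 20.7 and 15.3 CPM with P1 and P2. Without salt replicate 1, which held its 1 count in salt, the fitted log2 fold change was 13.43 instead of 11.31. JreChr05G10647 had no read in salt and from 0.845 ± 0.0572 CPM with P1 to 28.2 ± 2.08 CPM with P3 (edgeR adjusted p = 7.02e-22 for the mean of the strains). Its counts pooled over the strains were at least 301-fold higher than salt, a bound to which P3 and P4 gave the most counts. JreChr11G10472 had 200.2 ± 9.82 CPM in salt and from 2.34 ± 0.0653 CPM with P2 to 48.2 ± 1.93 CPM with P4 (log2 fold change -4.48 ± 0.04, SE, edgeR adjusted p = 3.28e-40). JreChr03G10163 had 20.5 ± 1.49 CPM in salt and from 0.737 ± 0.239 CPM with P3 to 2.14 ± 0.360 CPM with P2 (log2 fold change -4.26 ± 0.10, SE, edgeR adjusted p = 1.26e-27). At any size edgeR called 18545 genes, 53.0% of them higher. That share was 70.5% with library size only, where the median shifted by 0.211, and 48.2% with DESeq2's size factors.

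Some genes differed from salt in the same direction in all strain groups, and most of them were also salt-responsive. In all 4 strains, 1233 genes were 2-fold or more higher than in salt and 718 were 2-fold or more lower. Groups simulated at the salt level against the same salt libraries gave 0 such genes in each of 20 simulations. No strain effect was simulated, and each pair of strains shared 0 calls of 2-fold there too. The simulations therefore do not test how far real changes are shared between strains. Independent lists of these sizes would share 6.89 higher and 1.15 lower genes. Of the 1233 higher genes, 83.5% had fallen 2-fold or more in salt against control, and of the 718 lower genes, 93.5% had risen 2-fold or more. A smaller group, 124 higher and 18 lower genes, also differed 2-fold or more from control in every strain in the same direction. The counts of 1233 and 718 moved with the scaling, to 1592 higher and 479 lower with library size only and to 1135 higher and 821 lower with DESeq2's size factors. The smaller group was not recounted under other scalings. Part of these overlaps may come from the 3 salt libraries that the comparisons share.

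**Figure D3:**
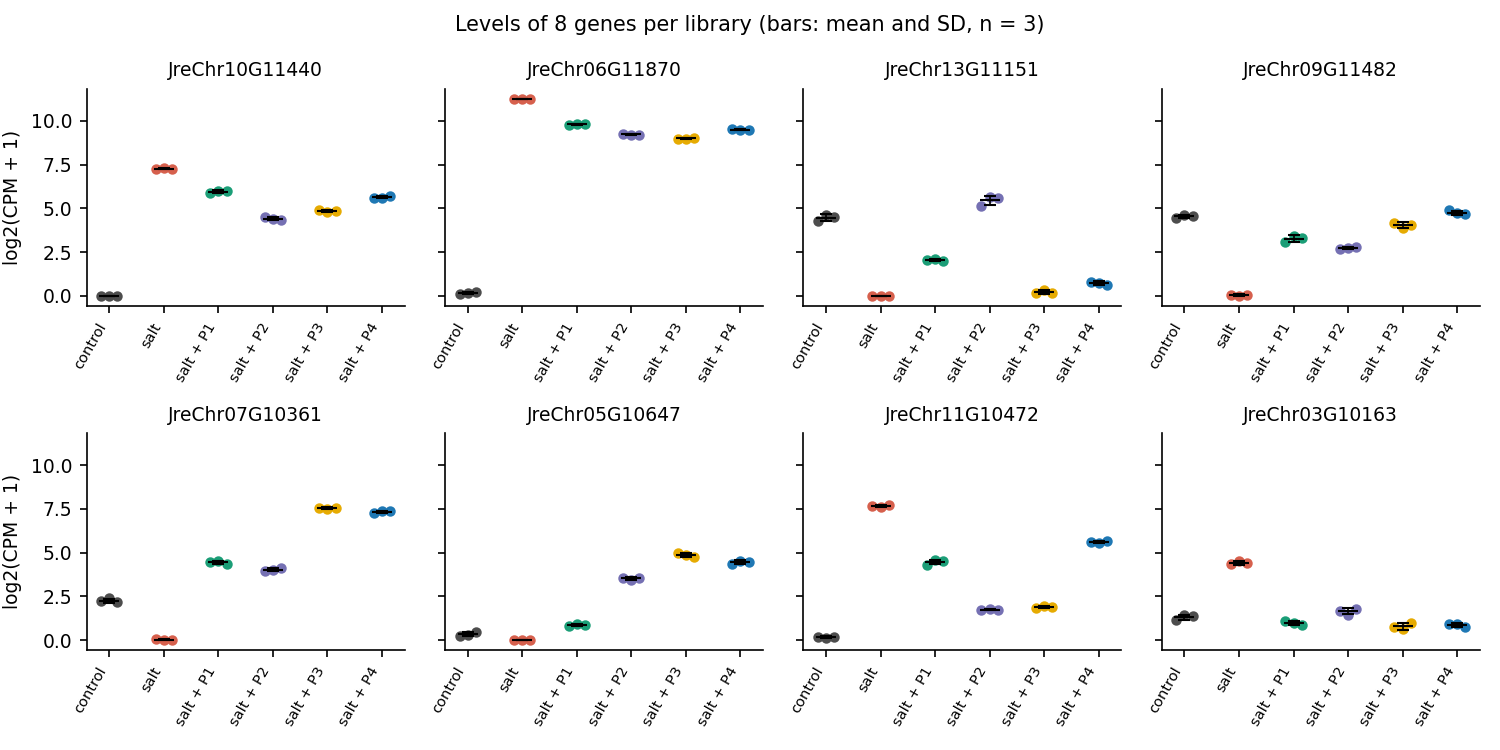
Level of 8 genes in each library as log2(CPM + 1), with 1 point per library and the mean and SD of each group of 3 as bars. The upper panels hold the genes named for salt against control and the lower panels those named for the mean of the strains against salt; JreChr06G11870 lies at 2424 CPM in salt and from 511 to 897 CPM in the strain groups.

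Whether salt-responsive genes lay back towards control in the strain groups was measured on the 9871 genes that salt had changed 2-fold or more. The greater part of these genes moved back with every strain: 6862 (69.5%) with P1, 7614 (77.1%) with P4, 8090 (82.0%) with P2 and 8247 (83.5%) with P3 were called against salt, at any size of change, in the direction opposite to the salt response. Those that moved back by 2-fold or more numbered 2373 with P1, 3743 with P4, 4492 with P2 and 5302 with P3, which is the greater part of the 9871 genes in P3 alone. Genes that moved further in the direction of the salt response numbered 523, 522, 466 and 533 in the same order. In all 4 strains 5911 genes (59.9%) moved back, and 810 genes (8.21%) moved back in none. Among the named genes, JreChr10G11440 was lower than in salt in each strain group, from 20.3 ± 1.06 CPM with P2 to 61.4 ± 2.80 CPM with P1. JreChr09G11482 regained 5.57 ± 0.267 CPM with P2 and 26.1 ± 2.25 CPM with P4, against 22.4 ± 1.28 CPM in control. JreChr13G11151 regained 43.5 ± 7.76 CPM with P2, and had 3.10 ± 0.154 CPM with P1, 0.661 ± 0.110 CPM with P4 and 0.166 ± 0.0945 CPM with P3.

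Among all 19762 genes called in salt against control, 11565 moved back with P1, 14403 with P2, 14446 with P3 and 13107 with P4. Both comparisons hold the same salt libraries, and groups simulated without an effect of a strain gave at most 4 such genes. Few genes could be called in such groups. That count therefore does not show how many of the observed genes the shared libraries added. Independent lists would give 5905, 7463, 7816 and 6923 genes. The covariance of the log2 fold changes of strain against salt and salt against control was -1.14 with P1, -1.75 with P2, -1.98 with P3 and -1.53 with P4, while the simulated covariances were -0.0318, -0.0334, -0.0328 and -0.0326.

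The return was partial in each strain. On a scale on which a gene's mean log2 CPM in control is 0 and in salt is 1, the median position of the 9871 genes was 0.729 ± 0.0024 (SD, n = 3) with P1, 0.616 ± 0.0016 with P4, 0.530 ± 0.00062 with P2 and 0.479 ± 0.0013 with P3. On this log2 scale, genes that salt had lowered lay nearer to control than genes that salt had raised. Their median positions were 0.334 against 0.581 with P3, 0.456 against 0.731 with P4, 0.465 against 0.598 with P2 and 0.668 against 0.780 with P1. On linear CPM by library size only, without TMM factors, the order was not the same. There the median share of the way back to control was 0.216 for lowered and 0.329 for raised genes with P1. It was 0.408 and 0.557 with P2, 0.373 and 0.414 with P4, and 0.574 and 0.562 with P3. With library size only on the log2 scale, lowered genes still lay nearer to control in each strain. Their positions were 0.632 against 0.824 with P1, 0.403 against 0.654 with P2, 0.274 against 0.666 with P3 and 0.463 against 0.778 with P4. The libraries of each pair of strains did not overlap in median position, and an exact two-sided permutation test gave p = 0.1 for each of the 6 pairs (Benjamini-Hochberg adjusted p = 0.1), which is the smallest value that 3 against 3 libraries allow. The share of genes beyond the control level, further from salt than control itself, was 1.97% with P1, 6.51% with P2, 7.93% with P4 and 12.5% with P3, counting positions more than 0.25 past control. Genes as far beyond the salt level made up 3.89% with P1, 3.79% with P2, 4.11% with P4 and 4.93% with P3.

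**Figure D4:**
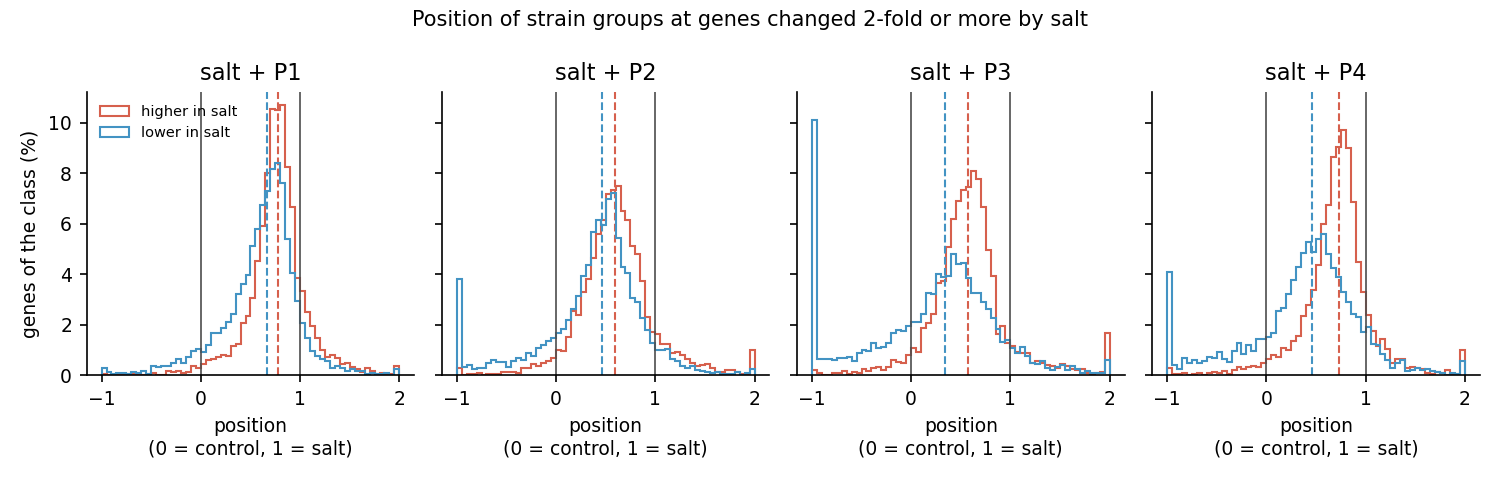
Distribution of the position of each gene between control (0) and salt (1) in the 4 strain groups, as per cent of the 4623 genes raised 2-fold or more by salt and of the 5248 genes lowered by salt. Dashed lines are medians over genes, and the end bins collect positions at or beyond -1 and 2; P3 has a median position of 0.479 over both classes and P1 of 0.729.

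Each strain against control measured how far inoculated salted seedlings stood from watered ones. The strain groups differed from control in 2-fold or more at 7266 genes with P1 (4103 higher, 3163 lower), 6514 with P2 (4198 higher, 2316 lower), 7294 with P3 (5199 higher, 2095 lower) and 7099 with P4 (4694 higher, 2405 lower), against 9871 for salt alone. JreChr10G11440 and JreChr03G11397 had no read in control, and the latter had none in salt either, yet 27.9 ± 1.1 and 79.2 ± 1.77 CPM with P3. At any size of change edgeR called 18491, 17943, 18946 and 18747 genes with P1 to P4. With library size only the median log2 fold change shifted by -0.114 with P1 and by -0.101 with P4, and the genes changed 2-fold or more divided into 3752 higher and 3728 lower with P1 and 4368 and 2887 with P4. In the same setting they were 4094 and 2446 with P2 and 5296 and 1994 with P3.

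Differences among the strains were tested directly. An F test of the equality of the 4 strain groups (edgeR) called 19906 of 24287 genes, 82.0%. Between pairs of strains, genes different by 2-fold or more numbered 1968 for P2 and P4, 2408 for P3 and P4, 2692 for P1 and P2, 2747 for P1 and P4, 2886 for P2 and P3 and 4516 for P1 and P3. P3 stood apart from the other strains by genes that were higher than in any other group: 674 genes were 2-fold or more higher in P3 than in each of the other 5 groups, all 5 tests being called, while 20, 41 and 24 genes did so for P1, P2 and P4. The groups without an inoculum had 1065 such genes in control and 671 in salt. The number fell to 433 with the stricter filter on low counts, which tests fewer genes. Genes lower than in each other group numbered 54 in P3, 30 in P1, 35 in P2 and 51 in P4.

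The 674 genes of P3 were of low to moderate level. Their median was 4.58 CPM in P3 (quartiles 1.75 and 12.7), 1.63 CPM in P4, 1.27 CPM in P2, 0.673 CPM in P1, 0.648 CPM in control and 0.328 CPM in salt. In P3, 594 of them had a mean of at least 1 CPM. Salt had lowered 283 of them 2-fold or more against control and raised 33, and the other 358 had a salt response of less than 2-fold or no call. P3 libraries also had the most genes with at least 1 CPM, by library size without TMM factors, 21801 ± 21.6 (SD, n = 3). The number was 21234 ± 42.2 in P2, 21203 ± 49.7 in P4, 20731 ± 2.08 in P1, 20576 ± 16.4 in control and 20181 ± 29.1 in salt. Their share of reads in the 10 highest genes was the lowest, 3.02% ± 0.0310. It was 3.49% ± 0.0912 in P4, 4.05% ± 0.0218 in P1, 4.46% ± 0.0563 in P2, 4.69% ± 0.0904 in salt and 5.52% ± 0.110 in control.

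**Figure D5:**
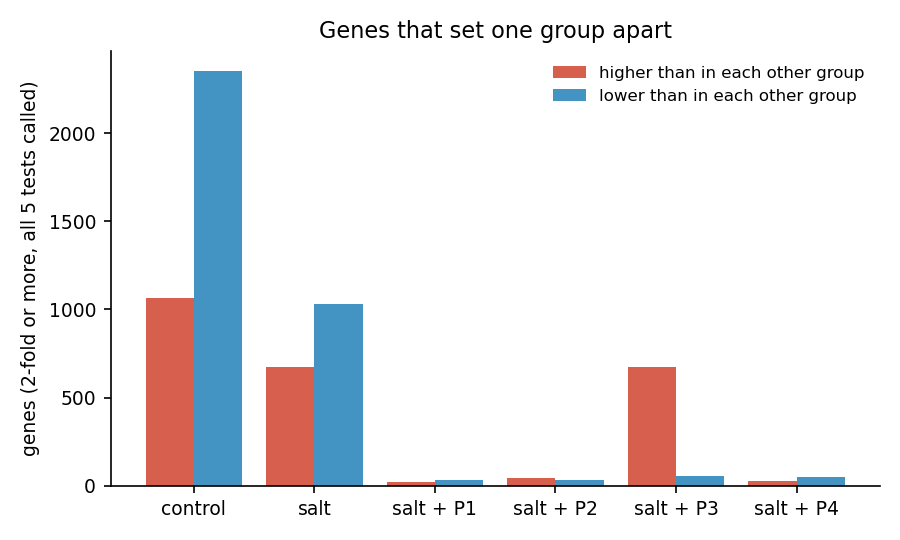
Number of genes that were 2-fold or more higher (red) or lower (blue) in one group than in each of the other 5 groups, with all 5 edgeR tests called. P3 has 674 such higher genes, the other strain groups have from 20 to 41, control has 1065 and salt has 671.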

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

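The tests of library scaling, both tests of mixing, the tests of sequencing depth, dominant genes, repeated deposition and shared pools, and the splits for single strains, for salt and for the mean of the strains, were chosen only after the results were seen. Some genes differed from salt in opposite directions in 2 strain groups, each 2-fold or more and with a called difference between the strains in edgeR. There were 27 such genes for P1 and P2, 56 for P1 and P3, 40 for P1 and P4, 44 for P2 and P3, 23 for P2 and P4 and 25 for P3 and P4. For comparison, 1585, 1927, 1430, 3332, 2256 and 3115 genes were changed 2-fold or more by both strains of these pairs, in either direction, with a called difference between the strains.

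The strain groups lay between control and salt at the salt-responsive genes. Noise in the shared salt libraries would move such genes back without any effect of a strain. Groups simulated at the salt level gave at most 4 genes moved back, against at least 11565 observed. No strain effect was simulated, so few genes could be called, and this count does not measure what shared libraries add to real changes. The covariance of the log2 fold changes rests on no calls. It was from -1.14 with P1 to -1.98 with P3, against simulated means from -0.0318 with P1 to -0.0334 with P2. Over 3 scalings the highest median position of a strain was 0.730, over raised and lowered genes together. By class, scaling moved the positions more. With library size only, salt-raised genes of P1 lay at 0.824 instead of 0.780 and salt-lowered genes at 0.632 instead of 0.668. Mixing of control RNA into salt RNA is not the whole cause, since 1.89% of tested genes in P1 and 10.6% in P3 lay 2-fold or more above both or below both, and since the share of control RNA that a salt gene needs lay a median of at least 3.67 standard errors from the median share in each strain, against 0.739 in a simulated mix. It stays open as a part, because on the log scale mixing also places salt-lowered genes nearer to control than salt-raised ones, as observed. However, the median shares were larger for raised than for lowered genes in P1 (0.329 and 0.216), P2 (0.557 and 0.408) and P4 (0.414 and 0.373). In P3 they were close (0.562 and 0.574). All these shares came from linear CPM by library size only, without TMM factors. A tray, harvest or library batch shared by a group is confounded with the group and stays open, and an effect of the inoculum on the salt response is a hypothesis that these libraries cannot separate from it.

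The 674 genes higher in P3 than in each other group were weighed against 3 technical explanations. P3 was not sequenced most deeply: its mean total was 0.925 of that of the deepest group. The smaller share of reads in its 10 highest genes could raise other genes by at most 1.03-fold. Under 2 other scalings the count was 720 or more. A response of the leaf to P3 may be the source, as may a batch shared by the P3 libraries, which cannot be told apart by this design.

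The spread between the libraries of a group was small. Libraries deposited more than once do not account for it, since the lowest chi-square per degree of freedom within a group was 1.93, above sampling noise. A shared pool of plants behind the 3 libraries of a group may give a coefficient of variation as low as the 3.52% observed, and this cannot be told apart from uniform plants, because the labels do not say what a replicate is. No biological explanation was tested.

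Other splits of the same libraries were fitted for each comparison. For the 9 comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In each of them 1 of the 10 splits, the real one, gave as many genes, with real counts of 19762 for salt against control, 14381, 18106, 19151 and 16944 for P1 to P4 against salt and 18491, 17943, 18946 and 18747 for P1 to P4 against control, and 0 as the highest of the other splits. For the mean of the strains against salt, 1 of 100 splits gave as many genes, with 18545 genes in the real split and 6792 as the highest other. For the test among the 4 strains it was likewise 1 of 100, with 19906 genes and 14274 as the highest other. The median of the other splits was 0 genes in both. These splits mix libraries of groups that lie far apart, which widens the fitted spread. Since the libraries of a group nearly coincide, the real split was likely to rank first for any difference between groups. Its rank therefore excludes no explanation, and says nothing on a batch or a pool of plants shared by a group.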

How the results depend on the processing

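Library size only, the test against a 2-fold change and the prior count of 0.5, and all alternatives for positions, for counts of changes of 2-fold or more and for group-specific gene sets, were chosen after seeing the data. The fold changes of the named genes kept their direction and their call in 120 values under other settings and 132 with a library left out, although without salt replicate 1 the fitted log2 fold changes of JreChr07G10361 rose to 12.01, 14.97 and 13.43 with P1, P4 and the mean of the strains. JreChr10G11546 did not pass the stricter filter, so its 4 comparisons have no value there. Of the counts of genes, 152 values under other settings and 210 with a library left out stayed within 1.5 times the main count, and 15 did not. Of these, 14 came from the test against a 2-fold change, which by construction asks for a larger effect. It called 8064 genes for salt against control, 1490, 4076, 5901 and 3531 for P1 to P4 against salt, 3737 for the mean of the strains, and 5553, 4871, 5714 and 5398 for P1 to P4 against control, and gave 1210, 3018, 3827 and 2431 salt genes moved back. The other was the number of genes higher in P3 than in each other group, 433 under the stricter filter, which tests fewer genes. Median positions moved by more than their very small spread between libraries in 56 values under other settings and 51 with a library left out, and by less in 4 and 57. Over raised and lowered genes together the order P1, P4, P2, P3 held in each setting. Within a class it did not: salt-lowered genes lay at 0.456 with P4 and 0.465 with P2, but at 0.463 and 0.403 with library size only, and salt-raised genes at 0.598 with P2 and 0.581 with P3, but at 0.654 and 0.666 with library size only. In the order P1 to P4 they were 0.719, 0.518, 0.471 and 0.606 without a filter, 0.737, 0.536, 0.482 and 0.621 with the stricter filter, 0.706, 0.493, 0.442 and 0.594 with library size only, and 0.731, 0.534, 0.486 and 0.620 with a prior count of 0.5. With DESeq2's size factors P2 was at 0.533 and P3 at 0.480, while P1 (0.730) and P4 (0.616) moved by less than their spread. The cause of the moves was not tested. With each library left out in turn the positions ranged from 0.726 to 0.731 with P1, 0.527 to 0.531 with P2, 0.477 to 0.482 with P3 and 0.612 to 0.618 with P4. The replicate numbers did not pair the libraries: deviations of libraries with the same number correlated at -0.0291 to 0.0348 over 45 pairs, and 7 of 18 libraries correlated best with their own number. A replicate block gave 19746 genes for salt against control and 14342 for P1 against salt, and changed no call of a named gene. Alternatives for the gene lists were not run, since the lists could not be tested. Depth limits the genes without a read in a group, whose fold is a lower bound.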

Other observations

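The tests of identifier order and of expression level had their criteria written before the results were seen, and the prior count of 0.5 was chosen after. The test of expression level was originally named for control level. It was renamed after its result was seen, with its criterion unchanged. Several genes left the range between control and salt. Genes called 2-fold or more above both control and salt numbered 315 with P1, 1085 with P2, 2198 with P3 and 1201 with P4, and genes below both numbered 143, 231, 365 and 272. Of the genes above both, 872 were called with P3 and no other strain, 608 with P2, P3 and P4 together, 335 with P3 and P4, 193 with P2 and P3, and 124 with all 4 strains. These sets do not test a difference between strains, and the sharing expected from the control and salt libraries that the comparisons have in common was not simulated. Another 22 genes had no read in control and salt but at least 1 CPM in a strain group. JreChr11G11718, chosen after its values were seen as the gene with the most reads, took 1.68% ± 0.112 (SD, n = 3) of the reads in control, 0.696% ± 0.0347 in salt, 0.561% ± 0.00931 with P1, 0.933% ± 0.0339 with P2, 0.569% ± 0.0158 with P3 and 0.736% ± 0.0275 with P4.

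The return towards control differed with the level of the gene. The level was the mean log2 CPM over all 18 libraries, those of the strains included. Among the 9871 genes changed 2-fold or more by salt, the median position was nearer to salt in the tercile with the highest mean level than in the tercile with the lowest, by 0.131 with P1, 0.138 with P2, 0.115 with P3 and 0.135 with P4. With a prior count of 0.5 the differences were 0.1240, 0.1246, 0.0910 and 0.1232, so that P3 passes the threshold of 0.1 only with the prior count of 2. In P3 this came from the salt-lowered genes, which lay at 0.0845 in the lowest tercile and 0.447 in the highest, while the salt-raised genes lay at 0.561 and 0.571. A hypothesis that the return depends on expression level met its criterion, a difference above 0.1 in every strain, with the prior count of 2. The smallest difference was 0.115. Level and position are not independent, since a return lowers the mean level of a salt-raised gene and raises that of a salt-lowered gene. In salt-raised genes this alone could give the direction seen. In salt-lowered genes it would give the opposite direction. Those lay, in the lowest and highest tercile, at 0.567 and 0.749 with P1, 0.360 and 0.547 with P2, and 0.348 and 0.515 with P4. Low counts and the prior count may also contribute.

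A hypothesis that responding genes group along the order of their identifiers was tested by permutation, taking that order as the order along chromosomes, which was not checked. Of the 674 genes higher in P3, 34 pairs were adjacent among tested genes, against a mean of 19.2 in 10000 permutations (permutation p = 8e-04). Of the 9871 salt genes, 2635 adjacent pairs changed in the same direction, against a mean of 2019 (permutation p = 1e-04, the smallest that 10000 permutations can give). Tandem gene copies that share reads may give the same grouping, and were not tested.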
